A study of Homo sapiens with 11 samples.

How the data were processed

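The data are 11 two-colour cDNA array hybridisations of total RNA from MCF7 and MDA-MB-231 cells, each against a universal human reference RNA. Groups were taken from the labels, as cell line, treatment and hours of exposure (24 or 48). Per the labels, the sample was in Cy5 on DIR arrays and in Cy3 on INV arrays. Nothing says that the arrays of a group came from separate cultures, so they were read as a technical dye swap and counted as 1 sample, which gave 6 samples. P-values measure only the spread between these samples, which may be technical or hold a real change from 24 to 48 h.

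The authors deposited 1 value per probe and array, and how it was made (scanner, background, normalisation, filters) is not given in the sources used here. From the values, 10 columns hold log2 ratios deposited by the authors and 1 column, the INV array of the MDA-MB-231 control, holds linear ratios (0.001 to 138, median 1.145), which were logged. Array medians ran from -0.83 on the DIR array of MCF7 48h to 0.20 on the logged array, so the authors had not centred every array; they were -0.26 (MCF7 control), -0.61 and -0.32 (MCF7 24h, DIR and INV), -0.83 and -0.46 (MCF7 48h), -0.00 and 0.20 (MDA-MB-231 control), 0.03 and 0.03 (24h), and -0.01 and 0.00 (48h). The arrays of a group correlated positively, so swapped arrays had already been turned. Each of the 10 log2 columns repeats a single highest value (15.5 to 17.3), as for a channel with no signal. Those values, above 15, were set to missing, a choice made after the values were seen. There were 354 on the MCF7 control array, 38 to 139 on 9 arrays and 0 in the linear column. Between 0 and 1276 probes per array had no deposited value. Without intensities, dim spots could not be removed.

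Of 13056 probes, 8047 were listed by the platform annotation with 1 gene, 276 with several, which were not used, and 4733 with none, which are unnamed here. Symbols were updated through Entrez identifiers (8035 of 8047 matched) with RefSeq names of GRCh38.p14, from which no coordinate was taken. Each array was centred on its median, probes of a gene with a value on the array were averaged (so that a probe missing on some arrays mixes probes), each gene's mean DIR minus INV difference was removed as its dye effect, and the arrays of a group were averaged. The 4325 genes were reduced to 4179 with a value in all 6 groups. Of genes with several probes, 7 had probes 2-fold apart in opposite directions at 48 h in MDA-MB-231. After the dye effect, the SD over genes of DIR minus INV was 0.58 and 0.70 in MCF7 24h and 48h, and 0.42 to 0.45 in the MDA-MB-231 groups. The dye effects of the 2 lines did not follow each other over genes (rho = -0.01), whereas the effect removed was a mean over the groups of both lines.

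Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05). Responses within a line and their difference came from 1 fit of 4 means (line by treatment) with 2 residual degrees of freedom, in which 24 and 48 h are the treated samples of a line and the single control is assumed to vary like them. The shared response had the line as a block and the line difference the condition. At a single time a gene was counted, without a test, when its log2 change was at least 1 (2-fold) and of the same sign and at least 1.5-fold in each orientation. The MCF7 control has no INV array, and its INV value is the DIR value less the dye effect. In MCF7 the demand on both orientations is therefore no independent second check of the control. Gene lists (p53 targets, NF-kB targets, gemcitabine transport and nucleotide metabolism, DNA replication, G2/M and mitosis, G1/S and E2F, DNA damage signalling and repair, apoptosis, interferon response, immediate early and stress, estrogen receptor targets, luminal markers, mesenchymal and basal markers, blood cell markers, ribosomal proteins, histones) were tested with camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the 16 lists. With an estimated correlation, camera also takes its degrees of freedom from the fit, 2 here (3 for the shared response). Calls are then hard to reach whatever the correlation. A list's median at 1 time was ranked among 10000 random lists matched on mean log2 ratio in 20 bins, without regard to correlation among list members.

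Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold with the same sign at both times (in both lines for the shared response). Missing places were filled, as values, by the largest fitted changes among genes with a log2 change of 1 or more at both times (for the lines, in all conditions). From each list it took the 4 largest members past the threshold, or else the 2 largest, and always RRM1, RRM2, DCK, CDA, CDKN1A, MDM2, NFKBIA and CXCL8 where measured. Not every list member so chosen is printed. Genes named at 24 or 48 h alone in MDA-MB-231, and in 48 against 24 h, were chosen after their values were seen.

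On simulated arrays with the measured noise and 4 classes of 50 changed genes, the 4-mean fit called 12 of 50 genes raised by 1 log2 and 37 of 50 raised by 2 log2 in MDA-MB-231, and 4 of 3962 unchanged genes, over 4179 genes tested. The 6-array fit at 48 h called 4 of 50 and 34 of 50, and 3 of 3962. The shifted list was called in each of the 3 responses and no other list was. Noise was drawn independently for each gene, with the same spread on every array. The simulation therefore does not cover lists whose members move together, differences between cultures, or a noisier control array. Changed genes were given the same change at 24 and 48 h. How many genes the 4-mean fit would call when their change differs between the times was thus not simulated. Without centring, the median log2 change over all genes was -0.44 for the MCF7 response, -0.26 for the shared response, 0.38 for the difference of response, 0.54 between the lines, and -0.34 and -0.54 in MCF7 at 24 and 48 h, and changes given are relative to the centred arrays. Alternatives covered centring, scaling of the spread (as limma does for log ratios) and quantile normalisation, probe and gene filters, the dye effect, single orientations, arrays left out, robust variance, arrays as separate samples, time points and the fold rule. Added after the values were seen were the capped values kept, dye effects within each line, the 6 MDA-MB-231 arrays alone, the MCF7 control array left out, treated samples only, only probes measured on all 11 arrays, and 48 against 24 h.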

Results

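Expression was measured on 11 two-colour cDNA arrays in the human breast carcinoma lines MCF7, an estrogen receptor positive line of luminal type, and MDA-MB-231, a receptor negative line of mesenchymal type. Cells were untreated or exposed to gemcitabine, a deoxycytidine analogue that blocks DNA synthesis, for 24 or 48 h. Each array set the RNA of 1 sample against a universal human reference RNA. Of the 6 groups, 5 had 2 arrays of exchanged dyes, DIR with the sample in Cy5 and INV with the sample in Cy3, which were counted as 1 sample. The MCF7 control had a DIR array only. The arrays held between 11698 and 13056 usable probe values, and 4179 genes had a value in every group. With 1 sample per group, the number of arrays limits the precision, and the spread between the arrays of a group may be technical.

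The array labelled MCF7 control stood apart from the other 10 arrays. Within it, different clones of a same gene correlated at a Spearman rho of 0.12 over 527 pairs (0.35 to 0.50 on the other arrays), clones spotted at 2 places at 0.51 (0.67 to 0.81), and the 50 spots of ACTN1 had a median absolute deviation of 1.15 (0.06 to 0.15). Over probes, its Spearman rho with them ran from 0.02 to 0.15, whereas the 4 arrays labelled MCF7 24h or 48h correlated at 0.66 to 0.83 with one another and at 0.60 to 0.73 with the INV arrays of MDA-MB-231, but at 0.32 to 0.39 with its DIR arrays. Among the MDA-MB-231 arrays rho was 0.74 to 0.84 between DIR arrays, 0.67 to 0.84 between INV arrays and 0.42 to 0.57 between DIR and INV arrays. Each INV array was closer to the arrays labelled MCF7 24h or 48h than to the DIR array of its own group (0.52 to 0.57). That the 2 arrays of an MDA-MB-231 group are a dye swap of 1 RNA is therefore an assumption, on which the MDA-MB-231 results rest. On the MCF7 control array the median log2 ratio of the luminal markers was 0.20 and that of the mesenchymal and basal markers was -0.58. On the 4 arrays labelled MCF7 24h or 48h, the luminal median lay between -0.75 and -0.44 and the mesenchymal median between -0.10 and 0.47, and on the MDA-MB-231 arrays the luminal median lay between -1.05 and -0.64 and the mesenchymal median between -0.22 and 0.09. Positive ratios are likely sample over reference, because the median of the blood cell markers was below 0 on all 11 arrays. It was -0.04 on the MCF7 control array and between -1.81 and -0.58 on the other 10. The luminal list was higher and the mesenchymal list lower on the MCF7 control array than in the MDA-MB-231 controls. That contrast bears on the direction only if the array's label is right. The luminal minus mesenchymal score of the 4 arrays labelled MCF7 24h or 48h (-1.03 to -0.57) lay within the MDA-MB-231 range (-1.10 to -0.42). Log base 2 was read from the values, and the centring applied by the authors stays unknown.

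**Figure D1:**
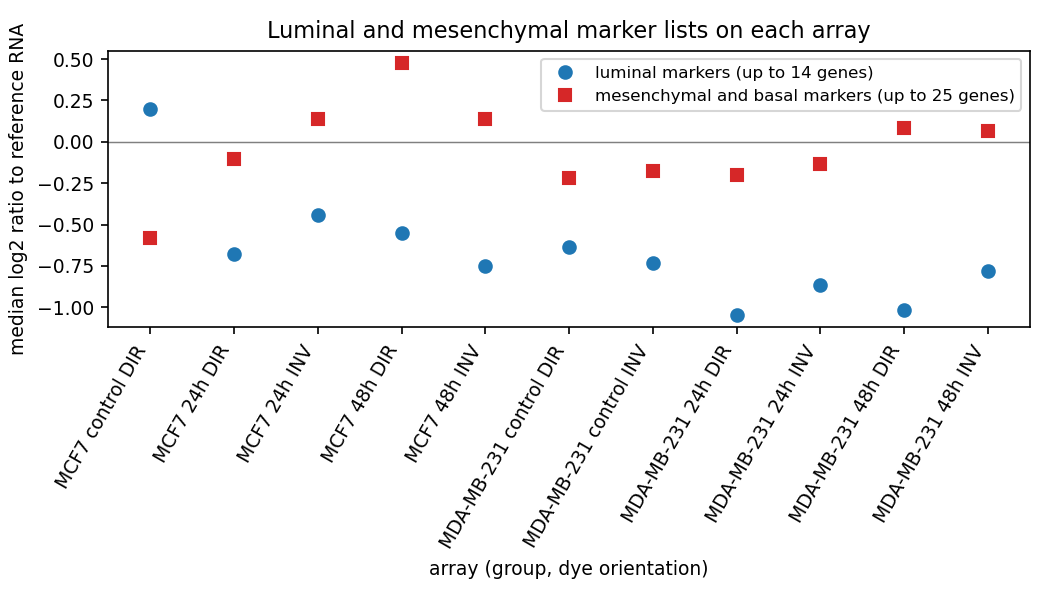
Median log2 ratio to the reference RNA (vertical axis) of the luminal markers (circles) and the mesenchymal and basal markers (squares) on each of the 11 arrays (horizontal axis, group and dye orientation). The luminal median was above the mesenchymal median on the MCF7 control array (0.20 against -0.58) and below it on the other 10 arrays.

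What MDA-MB-231 cells expressed after 48 h of gemcitabine was examined gene by gene. Single chemokine, cytokine and stress genes were far above control, and others were not. The neutrophil chemokine CXCL1 (Entrez gene 2919) was higher by 4.99 on the log2 scale (SE 0.09 between arrays; 4.93 in DIR and 5.04 in INV), its relatives CXCL2 and CXCL3 by 3.72 (2.0 by the CXCL2 probe measured on every MDA-MB-231 array) and 3.13, and the cytokine TNF by 4.01 (SE 0.38), whereas the chemokines CCL2 and CCL5 were at -0.29 and -0.06 and the cytokine IL1B at -0.33. ANKRD1, a muscle and stress-responsive repeat protein, was higher by 5.16 (SE 0.14). The secreted matrix proteins CCN2 and CCN1 were higher by 1.71 and 1.42, the plasminogen activator PLAU by 2.06, and the signalling regulator RGS2 by 2.76. Of the stress and early response genes, EGR1 was at 2.52, ATF3 at 2.48 (3.50 by its probe measured on every array), PPP1R15A, a phosphatase subunit of the stress response, at 2.59, and JUN at 1.31, while HSPA8 was at -1.22, MYC at -0.57 and FOS at 0.01. CDKN1A (Entrez gene 1026), which encodes the cell cycle inhibitor p21, was higher by 2.25 (SE 0.15; 1.99 in DIR and 2.51 in INV). Among the genes below control, the growth arrest gene GAS1 was at -1.46 (SE 0.07), the stress gene DDIT4 at -1.34 and the helicase DHX9 at -1.48. By size alone, without a test, 192 genes were at least 2-fold apart from control and at least 1.5-fold apart in each orientation, 120 higher and 72 lower (93 and 107 of 200 without centring of the arrays, 260 after scaling of the spread, 253 after quantile normalisation). In simulated arrays with the measured noise, the same rule took 62 of 3962 unchanged genes at this time. Without the DIR array of the control the count was 317, although both orientations of 48 h still had to pass, each against the 1 control array left. It was 301 without the DIR array of 48 h and 326 without its INV array, where a single orientation had to pass. A limma fit to the 6 MDA-MB-231 arrays, chosen after the values were seen, called 762 genes at an adjusted p under 0.05, 472 higher and 290 lower. It compares these RNA samples and not the conditions, since each condition is 1 sample. In it the adjusted p was 0.00599 for CXCL1, 0.015 for ANKRD1, 0.0206 for TNF and 0.0201 for CDKN1A. A fit over all 11 arrays called 12 genes.

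**Figure D2:**
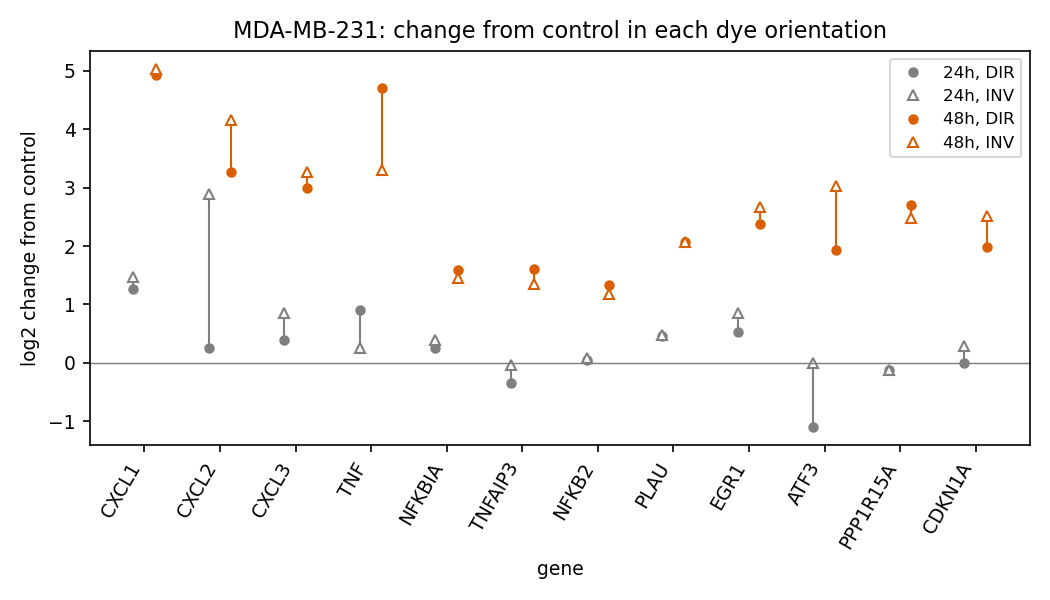
Log2 change from control (vertical axis) of 12 genes in MDA-MB-231 at 24 h (grey) and 48 h (orange), with circles for the DIR and triangles for the INV orientation and a line joining the pair. At 48 h the genes lay above control in both orientations, with CXCL1 at 4.93 and 5.04 and CDKN1A at 1.99 and 2.51. The values of CXCL2, ATF3 and TNFAIP3 mix probes.

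At 24 h the MDA-MB-231 values were closer to control. CXCL1 was higher by 1.37 on the log2 scale (1.27 in DIR and 1.47 in INV), RGS2 by 1.54, the collagen-related protein CTHRC1 by 1.63, the thiol transferase GLRX by 1.64 and RPS27L by 0.99. CDKN1A was at 0.14, TNF at 0.58 and PPP1R15A at -0.12. The transcription factor subunit GTF2A1 was at -1.59, the cytokinesis factor ECT2 at -1.51, and the helicases DDX3X and DHX9 at -1.17 and -1.18. At 48 h these genes were at -1.33, -1.08, -1.12 and -1.48. RELB, a subunit of NF-kB, was at -4.06, but its 2 probes were not both measured on every array, so the value mixes probes, and the probe with a value at both times was at -0.94 at 24 h and 0.59 at 48 h. By size 96 genes were apart from control, 44 higher and 52 lower (33 and 67 of 100 without centring, 88 and 69 of 157 after quantile normalisation, 160 after scaling of the spread), against 58 of 3962 unchanged genes in simulated arrays. With 1 array left out the count was 233 and 156 without the DIR and INV arrays of the control, and 243 and 182 without those of 24 h. The limma fit to the 6 arrays called 242 genes, 151 higher and 91 lower, and the fit to all 11 arrays called 0, with 459 genes at an unadjusted p under 0.05. In that fit to the 6 arrays the adjusted p was 0.0439 for CXCL1, for CTHRC1 and for GTF2A1. Between 48 and 24 h, without use of the control, 77 genes were 2-fold apart, 64 higher and 13 lower at 48 h, and the 6-array fit called 20, 19 of them higher. ANKRD1 was higher at 48 than at 24 h by 4.23, CXCL1 by 3.62, and TNF by 3.43, and GAS1 and DDIT4 were at -1.08 and -1.17.

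The changes at 24 and 48 h in MDA-MB-231 correlated over genes at r = 0.66, where unchanged groups simulated against a shared control gave 0.50 (genes are not independent replicates). The covariance was 0.159 against a simulated 0.0457. With different control arrays for the 2 times, r was 0.41 and 0.29. By size 23 genes were higher and 22 lower at both times, and both times used the same control.

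Groups of genes in MDA-MB-231 were followed with the gene lists. Ranges of list medians in brackets span the 4 ways of scaling the arrays (centred, not centred, scaled to a common spread, quantile normalised). Random lists were drawn without regard to correlation, so members that move together in 1 culture can reach extreme percentiles. Among the NF-kB targets the correlation was estimated at 0.45. That estimate rests on the differences between 24 and 48 h, so it also holds any common change of the list between these times. Over all genes, the 6-array fit called 5.79% at 24 h and 18.2% at 48 h. Of the 29 NF-kB targets measured, 22 were above control at 48 h, with a median log2 change of 0.57 (0.38 to 0.57) that lay at the 99.99th percentile of 10000 random lists. The 6-array fit called 12 of them higher and 0 lower (20 when adjusted over the list alone), among them NFKBIA, the inhibitor of NF-kB, at 1.52, the deubiquitinase TNFAIP3 at 1.48, the subunit NFKB2 at 1.26 and the superoxide dismutase SOD2 at 1.61. At 24 h the median of the same list was 0.00 (-0.06 to 0.01), and CXCL1 was called higher and RELB, a mixture of probes, lower (3 calls over the list alone). CXCL8 had no measured value. Immediate early and stress genes had a median of -0.18 at 24 h (-0.24 to -0.03) and 0.26 at 48 h (0.16 to 0.36; 98.4th percentile), with 7 of 19 members called higher, such as JUND at 1.40, and 4 lower at 48 h (13 over the list alone). At 24 h 0 were called, and 6 when adjusted over the list alone. Of 21 p53 targets, 5 were called higher at 48 h and 0 lower, including CDKN1A, SESN1 at 1.03 and the death receptor FAS at 1.11 (1.52 by 1 of its probes). Over the list alone 7 were called. The p53 list's median was 0.16 at 48 h (0.06 to 0.35) and 0.01 at 24 h (-0.05 to 0.07), where SESN1 at 0.72 was the 1 member called. MDM2, the p53 antagonist, was not called at 48 h (adjusted p of 0.115 in limma), and its 7 probes differed among themselves. Interferon response genes had a median of 0.19 at 48 h (0.09 to 0.20; 98.9th percentile) with 5 of 27 members called higher and 1 lower (7 over the list alone). The proteasome subunit PSMB8 was at 0.76 at 48 h and, the 1 member called at 24 h, at 0.84. The interferon median at 24 h was 0.03 (-0.04 to 0.08).

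The G2/M list in MDA-MB-231 had a median log2 change of -0.21 at 24 h (-0.28 to -0.21; 0.20th percentile) and -0.14 at 48 h (-0.28 to -0.14; 2.88th percentile), with 9 of 25 members above 0 at both times, and camera did not call it over both times (adjusted p = 0.439, and 0.863 with an estimated correlation). Of its members, 1 was called higher and 2 lower at 24 h by the 6-array fit (11 over the list alone), and 2 higher and 5 lower at 48 h (8 over the list alone). The mitotic kinases PLK1 and AURKA were at -1.23 and -0.67 at 48 h, and the tubulin-binding protein STMN1 was at 1.25. DNA damage signalling and repair genes had medians of 0.09 (0.02 to 0.09) and 0.12 (0.02 to 0.12), with 1 member called higher and 1 lower at 24 h and BRCA1 and DDB1 at 0.85 and 0.60 among 2 higher and 1 lower at 48 h. DNA replication genes had medians of 0.02 (-0.05 to 0.02) and 0.06 (-0.04 to 0.09), and RPA2, a subunit of a single-strand binding complex, was called higher at both times, by 1.02 and 1.01. G1/S and E2F genes had medians of 0.01 (-0.06 to 0.14) and 0.03 (-0.06 to 0.08), with 2 called lower at 24 h and 2 higher and 3 lower at 48 h, where the G1 cyclin CCND1 was at -1.48. For the list of gemcitabine transport and nucleotide metabolism the medians were 0.03 (-0.03 to 0.03) and 0.06 (-0.06 to 0.06), with 1 call at 24 h and 3 at 48 h. Its members RRM1 and RRM2, the subunits of ribonucleotide reductase, were at 0.33 and 0.16 at 48 h, DCK, which phosphorylates gemcitabine, at 0.35, and CDA, which deaminates it, at -0.20, without a call. DUT, the dUTPase of the same list, was called higher at both times, by 0.73 and 0.60. The 8 ribosomal protein genes had medians of 0.45 at 24 h (0.38 to 0.67; 99.9th percentile) and 0.30 at 48 h (0.20 to 0.50), with RPL11 at 0.67 and 0.70 among 3 and 2 members called higher.

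In the remaining lists in MDA-MB-231, apoptosis genes had medians of -0.01 (-0.08 to 0.07) and 0.05 (-0.05 to 0.10), and 5 of 32 were called higher and 0 lower at 48 h (9 over the list alone, and 0 at 24 h), such as the death promoting genes HRK at 1.18 and BIK at 0.97. Estrogen receptor targets had medians of -0.20 (-0.27 to -0.05) and -0.44 (-0.54 to 0.14), and 1 was called lower at 24 h (2 over the list alone) and 2 higher and 3 lower at 48 h (6 over the list alone). Luminal markers had medians of -0.00 (-0.07 to 0.11) and -0.17 (-0.27 to 0.06), and 1 was called lower at 24 h (2 over the list alone) and 1 higher and 3 lower at 48 h (8 over the list alone). Mesenchymal and basal markers had medians of -0.08 (-0.15 to 0.11) and 0.03 (-0.07 to 0.17), and 0 were called higher and 2 lower at 24 h (8 over the list alone), and 4 higher and 0 lower at 48 h (4 over the list alone), PLAU, CCN2, CCN1 and the receptor PLAUR at 1.06. Blood cell markers had medians of -0.05 (-0.11 to 0.16) and -0.07 (-0.17 to 0.15), and CD74, an antigen presentation chaperone, was called higher at both times, by 0.98 and 1.64. Histones had medians of -0.14 (-0.21 to -0.12) and 0.14 (0.04 to 0.40), and 1 was called higher at 24 h and 1 higher and 1 lower at 48 h.

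**Figure D3:**
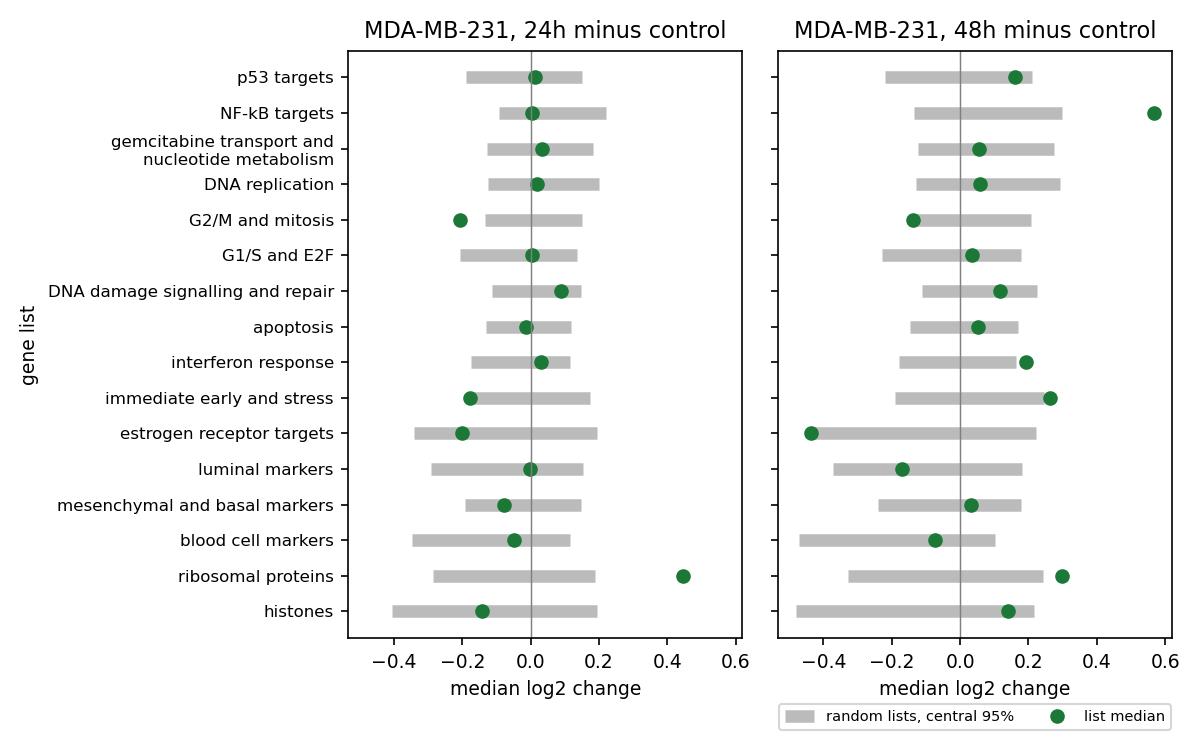
Median log2 change from control (horizontal axis) of each of the 16 gene lists (vertical axis) in MDA-MB-231 at 24 h (left) and 48 h (right). Green points are list medians and grey bars hold the central 95% of the medians of random lists, and the NF-kB targets lay at 0.00 at 24 h and 0.57 at 48 h.

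With the 24 and 48 h samples taken as the 2 treated samples of MDA-MB-231, no gene passed the limma test on the 6 sample values (0 genes, 503 at an unadjusted p under 0.05, lowest adjusted p 0.323). The spread in this test is that between 24 and 48 h, so a real change between these times counts as noise. The lack of calls therefore does not show that the cells did not respond. The fit to 11 arrays called 2 genes and the fit to the 6 MDA-MB-231 arrays 765. The genes with the largest fitted values at both times were CXCL1 at 3.18 (SE 1.47), CXCL2 at 2.64, ATG4C at 2.37, KLF8 at 2.15, RGS2 at 2.15, OPTN at 2.11, NBPF14 at 1.90 and CTHRC1 at 1.78 above control. Below control were HACD4 at -3.62, RELB at -2.96, CCR1 at -2.28, LMO7DN at -2.27, CNP at -2.14, UBD, DNAJC16 at -1.87 and PGF at -1.78. Several of these did not hold by orientation or by probe. CXCL2, OPTN, HACD4, RELB, CCR1, CNP, DNAJC16 and PGF had a probe without a value on some MDA-MB-231 array, and by the probe measured on all of them CCR1 was at -0.43 and -0.78 at 24 and 48 h and CXCL2 at 0.63 and 2.0. At 48 h OPTN was at -0.18 in DIR and 4.50 in INV and LMO7DN at -4.60 and 0.10, CNP had opposite signs at 24 h, and 1 of the 2 probes of PGF was at -0.02. The RELB value mixes probes, and the probe with a value at both times (-0.94 and 0.59) did not fall at both. Among list members, the largest values included PLK1 at -1.19, CCND1, a G1 cyclin, at -1.20, RPA2, a subunit of a single-strand binding complex, at 1.02 and CD74 at 1.31, without a call. ERCC5 at -0.94, FADD at -1.07 and XIAP at 1.07 had opposite signs in DIR and INV at 24 h (0.50 and -2.15, 0.20 and -1.78, -0.47 and 2.07). Adjusted over the list alone, 1 DNA replication gene and 2 G2/M genes passed and 0 of each of the other lists. Of the 16 lists, camera with a preset correlation called ribosomal proteins higher (adjusted p = 0.0269), a call lost with an estimated correlation (adjusted p = 0.863) and, with the preset one, without the INV array of the MDA-MB-231 control (0 lists), while 2 lists were called without the DIR array of MCF7 48h or that of MDA-MB-231 24h. NF-kB targets reached an adjusted p of 0.187, and of 0.863 with an estimated correlation.

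In MCF7, the samples labelled 24h and 48h were set against the single array labelled MCF7 control, the array that stood apart and on which different clones of a same gene correlated at 0.12. The SEs and p-values rest on the spread between 24 and 48 h in the 2 lines and hold none of that array's own noise. Its ACTN1 spots had a median absolute deviation of 1.15, against 0.06 to 0.15 on the other arrays, so the SEs are likely too small. The limma test called 2017 genes, 984 higher and 1033 lower in the treated samples. Among the genes that rose, ONECUT1, a liver and neural transcription factor, rose by 6.42 on the log2 scale (SE 0.24, adjusted p = 0.00176), OTUD1 by 5.58 (-1.19 if values at the array maximum were kept), the annexins ANXA3 and ANXA1 by 5.30 and 5.13, the cytokine signalling suppressor CISH by 4.96, SH3KBP1 by 4.78, DCAF7 by 4.73 and the tubulin TUBA1A by 4.67. Among those that fell, NCLN was at -7.23 (SE 0.19, adjusted p = 0.00176), SPG7 at -6.90, NTN4 at -6.79, FILIP1L at -6.52, NRCAM at -6.39, TTC14 at -6.38, IL13RA2 at -5.73 and ITM2A at -5.67. By size alone 1505 genes were apart from control at 24 h, 744 higher and 761 lower (525 and 1080 of 1605 without centring), and 1532 at 48 h, 758 higher and 774 lower (426 and 1290 of 1716). The 2 times shared 629 higher and 626 lower genes, and both used the same control array. Without centring of the arrays the split of the 2104 genes called was 607 higher and 1497 lower, with a median log2 change over all genes of -0.44, and without the DIR array of MCF7 48h the count was 1275. Without the control array no comparison can be made.

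Single markers of cell type and of proliferation differed from the control array in this comparison. Camera called neither the luminal list nor the mesenchymal and basal list. Luminal markers fell in 9 and rose in 2 of 14 measured genes, with TFF1 at -4.78, ERBB3 at -3.58, KRT8 at -3.58 and the transcription factor FOXA1 at -2.12. Mesenchymal and basal markers rose in 11 and fell in 3 of 25, with ANXA1 at 5.13, the protease MMP14 at 4.54 and the collagen COL4A2 at 3.18 higher and the fibronectin FN1 at -4.35 lower. Over the list alone 11 luminal and 15 mesenchymal genes passed. The luminal median on the control array was 0.20, against -0.75 to -0.44 on the treated arrays. Camera called 3 lists with the preset correlation and none of them with an estimated one (adjusted p = 0.355 for DNA replication and for G2/M, and 0.432 for blood cell markers). With the preset one, DNA replication genes (adjusted p = 0.000169) rose in 14 of 17 members and fell in 0, such as the clamp PCNA by 2.71, RFC2 by 3.02 and RPA1 by 2.36. G2/M genes (adjusted p = 0.000169) rose in 18 of 25 and fell in 2, such as UBE2C by 3.48 and PTTG1 by 3.23. Blood cell markers (adjusted p = 0.0301) fell in 9 of 14 and rose in 0, with LCP1 at -4.62 and LYZ at -3.86. Over the list alone 14 DNA replication, 21 G2/M and 11 blood cell genes passed. The blood cell median was -0.04 on the control array and -1.81 to -1.34 on the treated ones.

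The other lists were not called in MCF7, although single members passed. In most of these lists they did so at about the share of all genes (48.3%), so the counts do not set the lists apart. Among genes of gemcitabine metabolism, 7 of 19 rose and 3 fell, with RRM2 higher by 2.46 (SE 0.17), the phosphorylase PNP by 2.45 and RRM1 by 1.62, CDA at -0.73, and DCK not called at -0.21. Of 21 p53 targets 5 rose and 7 fell (13 passed when adjusted over the list alone), with CDKN1A at -3.55 (SE 0.87), TP53INP1 at -3.28 and MDM2 at -1.16 lower and SFN higher by 3.12. Of 29 NF-kB targets 7 rose and 5 fell, with BIRC2 at 3.45 and PLAU at 2.67 higher, IL1A at -2.88 and CCL2 at -2.86 lower, and NFKBIA at 0.56 not called. DNA damage genes rose in 9 and fell in 3 of 28, led by DDB1 at 3.12. Apoptosis genes rose in 6 and fell in 9 of 32, interferon response genes rose in 8 and fell in 6 of 27 and immediate early genes rose in 5 and fell in 3 of 19. Estrogen receptor targets rose in 1 and fell in 4 of 11, G1/S genes rose in 2 and fell in 4 of 19, ribosomal proteins rose in 1 and fell in 3 of 8 and histones rose in 3 and fell in 4 of 7. Adjusted over the list alone, 11 genes of gemcitabine metabolism passed, 12 NF-kB targets, 11 DNA damage, 15 apoptosis, 15 interferon, 8 immediate early, 5 estrogen receptor, 2 G1/S, 6 ribosomal and 7 histone genes. All of these rest on the control array with a luminal median of 0.20.

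Set against each other without the control, the MCF7 samples at 48 and 24 h were closer. By size 64 genes were apart, 40 higher and 24 lower at 48 h, in a comparison added after the values were seen and without a test. The serpin SERPINB3 was higher at 48 h by 2.62 on the log2 scale (2.20 in DIR and 3.04 in INV), PLAAT4 by 2.27, USP45 by 2.11 and the cyclin CCNG2 by 1.81. The chemokine CXCL9 was at -2.38, FABP3, a fatty acid carrier, at -2.11 and RRAD at -1.90. Over genes these changes had an r of 0.02 (genes are not independent replicates) with those from 24 to 48 h in MDA-MB-231.

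A response common to both lines was tested with the line as a block. No gene passed (0 genes in limma, 660 at an unadjusted p under 0.05, lowest adjusted p 0.307), and the fit to 11 arrays as separate samples called 1274. Differences of response between the lines, and between 24 and 48 h, count as spread in the limma test. Adjusted over the list alone, 1 G2/M gene passed and 0 of each of the other lists. The largest values with the same sign in both lines and at both times were CXCL1 at 3.04 (SE 0.96), KLF8 at 2.63, CXCL2 at 2.46, PLA2G7 at 2.33, TCEAL9 at 1.97, CTHRC1 at 1.82, PCLAF at 1.51 and IFT25 at 1.27 above control. Below control were PLAG1 at -2.99, SOX3 at -2.70, ALDH1A1 at -2.47, UBD at -2.17, CCR1 at -2.13, MAN1A1 at -2.03, NFIA at -2.02 and SLC43A3 at -1.97. The CXCL2 and CCR1 values mix probes. Camera called DNA replication (adjusted p = 0.00131) and G2/M genes (adjusted p = 0.0221) higher, both lost with an estimated correlation (adjusted p = 0.650), while NF-kB targets had an adjusted p of 0.0767. Without the DIR array of MDA-MB-231 24h 5 lists were called, and without that of the MDA-MB-231 control 1. In MDA-MB-231 alone these lists had medians of 0.00 and -0.17. Over genes, the mean responses of the lines correlated at r = 0.14.

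The difference of response between the lines was tested as an interaction. It passed for 1214 genes, 618 with a more positive change in MDA-MB-231 and 596 with a more positive change in MCF7. SPG7 (6.64, SE 0.83), NCLN (6.25), NTN4 (5.94), TTC14, FILIP1L, POLR3E, TMEM101 and ACAP3 had the largest positive differences, and RELB (-5.91, a mixture of probes), VCAN (-5.62), ONECUT1 (-5.51), HACD4, DCAF7, CISH, ANXA3 and PIEZO1 the largest negative ones. CDKN1A, called lower in MCF7 and not called in MDA-MB-231 (1.20, adjusted p = 0.632), differed by 4.75 (SE 1.22, adjusted p = 0.0477). TFF1 differed by 4.40, ERBB3 by 3.60, RRM2 by -2.26, UBE2C by -3.37 and ANXA1 by -4.14. NFKBIA (0.35), MDM2 (0.16), DCK (0.43) and CDA (0.54) did not pass. Camera called G2/M (adjusted p = 0.000152) and DNA replication genes (adjusted p = 0.00113) lower and blood cell markers higher (adjusted p = 0.0126) in the difference, with 1 member called higher and 14 lower, 0 and 6, and 6 and 0 (18, 10 and 9 calls over the list alone). None held with an estimated correlation (adjusted p = 0.437, 0.437 and 0.447). Members of the other lists were called higher and lower in the difference in numbers of 5 and 3 for p53 targets, 3 and 3 for NF-kB targets, 0 and 6 for gemcitabine metabolism, 2 and 1 for G1/S, 1 and 6 for DNA damage, 3 and 3 for apoptosis, 6 and 6 for interferon response, 0 and 3 for immediate early, 2 and 2 for estrogen receptor, 6 and 2 for luminal, 3 and 7 for mesenchymal, 4 and 1 for ribosomal and 2 and 2 for histone genes. Over the list alone the calls were 8, 4, 7, 0, 6, 2, 13, 1, 5, 8, 11, 5 and 7 in that order. The MCF7 side of every difference rests on the array labelled MCF7 control, and the SEs and p-values hold none of that array's own noise. Without centring 1141 genes passed, 796 of them positive and 345 negative. Without the DIR array of MCF7 48h 265 passed, without the INV array of MCF7 24h 717, and with DIR arrays only 786.

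The lines themselves were compared at matched conditions. No gene passed (0 genes in limma, 348 at an unadjusted p under 0.05, lowest adjusted p 0.563), 0 passed with the treated samples only, and the fit to 11 arrays called 981. The test had 2 residual degrees of freedom. On the MCF7 side, the treated arrays had marker scores within the MDA-MB-231 range, and the control is the array that stood apart. The lack of calls therefore does not show that the lines are alike, and the values below hold only if the labels are right. Of genes apart in all conditions, the growth factor FGF18 was at 2.97 (SE 0.97), the chemokine CXCL13 at 2.96, CISH at 2.81, ZCCHC12 at 2.70, SELE at 2.48, CENPW at 2.24, RHOBTB1 at 2.12 and the histone H4C3 at 2.11, higher in MDA-MB-231. GASK1B at -3.66 (SE 0.59), KIFC2 at -3.01, UBE2D4 at -2.93, CDH19 at -2.66, ZNF3 at -2.40, STK4 at -2.32, TRADD at -2.31 and PSMA6 at -2.28 were lower. These are values and not calls, and SELE, GASK1B, CDH19, ZNF3, STK4 and PSMA6 had a probe without a value on some MDA-MB-231 array.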

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

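The tests of the MCF7 control array in this part were chosen after the result was seen, and the interaction and the splits of samples before. The interaction of line and treatment was past its threshold in 1214 genes, and the largest differences of log2 response, MDA-MB-231 less MCF7, drew attention because the change differed between the lines. They were 6.64 for SPG7, 6.25 for NCLN, 5.94 for NTN4, 5.77 for TTC14, 5.71 for FILIP1L, 5.56 for POLR3E, 5.35 for TMEM101 and 5.26 for ACAP3. In the other direction they were -5.91 for RELB (a mixture of probes, of which the 1 with values at both times was at -0.94 and 0.59 in MDA-MB-231), -5.62 for VCAN, -5.51 for ONECUT1, -5.24 for HACD4, -4.88 for DCAF7, -4.82 for CISH, -4.64 for ANXA3 and -4.62 for PIEZO1.

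The array labelled MCF7 control stood apart from the other arrays, and the 1214 differences and the 2017 MCF7 calls use it. Values out of order at random are argued against by clones spotted at 2 places, which correlated at a Spearman rho of 0.51 within that array (0.67 to 0.81 on the others), and spot noise alone by its rho of 0.0716 with the DIR array of MCF7 24h, where noise of that size would leave about 0.69, and noise as wide as among its 50 ACTN1 spots (median absolute deviation 1.15, against 0.06 to 0.15 elsewhere) about 0.30. Values out of order with repeated clones moved together stay open, since different clones of a same gene correlated at 0.119 over 527 pairs (SE 0.0437), above 0 but below the 0.28 that the noise of the array would leave and the 0.35 to 0.50 on the others. A label that does not match the RNA stays open too. The luminal minus mesenchymal score of all 4 arrays labelled MCF7 24h or 48h lay within the range of the MDA-MB-231 arrays. That of the control array (0.78) lay outside it. The rho of those 4 arrays was 0.60 to 0.73 with the INV arrays of MDA-MB-231 and 0.32 to 0.39 with its DIR arrays. The INV and DIR arrays of MDA-MB-231 themselves correlated at only 0.42 to 0.57. The lower rho with the DIR arrays therefore does not decide the question. A response to gemcitabine cannot be told apart from the array itself with 1 control array, and the responses of the lines correlated at r = 0.14.

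For the comparison of MDA-MB-231 with MCF7, the 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 genes and the highest other called 40, in each of 2 splits that put the treated samples of 1 time, from both lines, with the MCF7 control.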

How the results depend on the processing

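Alternatives named here as added (values at the array maximum kept, dye effects within each line, 6 MDA-MB-231 arrays, no MCF7 control array, treated samples only, only probes measured on all 11 arrays) were chosen after the data were seen. Cultures could not be paired, because the replicate numbers only name the dye orientation, which was a term in the fits to single arrays. The array values came without intensities, so dim spots could not be weighed.

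The count for MCF7 (2017) stayed within 1.5 times under the other settings except each probe on its own (3732, since more features are tested) and the arrays left out in turn (1275 to 2032). The difference of response (1214) became 2307 with each probe on its own, 786 with DIR arrays only and 265 to 1369 with arrays left out. For MDA-MB-231 (0) the counts were 1 with each probe, 1 with INV arrays only, 2 with 11 arrays as separate samples, 765 with the 6 MDA-MB-231 arrays, and 0 to 0 with arrays left out. Treating arrays as samples replaces the spread between samples by that between dye orientations. The shared response (0) became 1274 and the line difference (0) became 981 with 11 arrays as separate samples, and both were 0 with arrays left out in turn. The line difference was 0 without the condition block and 0 with treated samples only.

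Counts by size in MCF7 were 2910 at 24 h and 2887 at 48 h with each probe, and 1471 to 1626 and 1503 to 1746 with arrays left out. In MDA-MB-231 at 24 h (96) they were 160 with scaling of the spread, 157 with quantile normalisation, 173 with each probe, 167 with DIR and 258 with INV arrays only, 289 at 1.5-fold, and 91 to 243 with arrays left out. At 48 h (192) they were 354 with each probe, 289 with DIR and 311 with INV arrays only, 491 at 1.5-fold, and 184 to 326 with arrays left out. A single orientation drops the demand that both orientations pass. Without the MCF7 control array they were 96 and 197, and the test of MDA-MB-231 called 0, while the MCF7, shared and difference results could not be computed.

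Lists called for the shared response (2) were 4 without centring, 1 with scaling of the spread, 1 with quantile normalisation, 8 with each probe, 1 with values at the array maximum kept, and 1 to 5 with arrays left out. For MDA-MB-231 (1) they were 2 without centring, 2 with each probe, 0 with DIR arrays only and 0 to 2 with arrays left out. For MCF7 (3) they were 5 with each probe and 2 to 4 with arrays left out, and for the difference (3) 6 and 2 to 4. With an estimated correlation the count was 0 in each of the 4. The estimate was 0.01 for ribosomal proteins in MDA-MB-231, and -0.04 and -0.02 for DNA replication and G2/M genes in MCF7. Correlation among these genes therefore does not account for the loss of those calls, and few residual degrees of freedom were left. In the shared response the estimates were 0.37 for DNA replication and 0.38 for G2/M genes, so correlation may play a part in the loss there. The cause was not tested for the other list counts.

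With values at the array maximum kept, OTUD1 turned to -1.19, CDKN2A to -7.52 and HSPA8 to -1.05 in MCF7, and CCND1 to 2.71 and HSPA8 to 0.31 in the difference of response, because values above 15 then enter the means. Counting each named gene under each alternative once, calls were lost in 34 for MCF7 and 81 for the difference, and gained in 1 for the difference, 27 for MDA-MB-231, 42 for the shared response and 12 between the lines. Values without a call moved by more than their SE in 2 for MCF7, 4 for the difference, 46 for MDA-MB-231, 17 for the shared response and 34 between the lines. Among the named genes, no other call changed sign. Signs of the remaining called genes were not followed. With only probes measured on all 11 arrays, the counts were 2216 for MCF7, 1552 for the difference, and 72 and 167 by size in MDA-MB-231 at 24 and 48 h.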

Other observations

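The subunit list and the tests of the single orientation for NF-kB targets and of message length in this part were chosen after the result was seen. Nuclear genes for oxidative phosphorylation subunits stood above control in MDA-MB-231 at both times. Of 31 measured, 29 were higher at 24 h and 29 at 48 h, with a median log2 change of 0.69 and 0.58, while random lists of like ratio lay between -0.10 and 0.15 at 24 h. At 24 h the members ranged from -0.02 for SDHA and NDUFV1, 0.12 for COX7A1, 0.23 for NDUFS1 and 0.26 for NDUFB7, through 0.69 for ATP5F1C, to 1.20 for UQCRQ and 1.22 for NDUFB3. In the samples labelled MCF7 the list's medians were 0.20 and 0.33, at percentiles 79.6 and 86.1 of random lists.

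An effect of 1 dye orientation is argued against for these subunits, as the lower of the medians by orientation at 24 h was 0.62. A trend with the genomic span of genes is argued against too, because subtracting the median of genes of like span left 0.66. Span is not the length of the message, however. Message length may play a part, since ribosomal proteins, another group of short messages, had a median of 0.45 at 24 h. The tables hold no message lengths, so a difference in RNA integrity or labelling and a response of the cells both stay open.

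The median of the NF-kB targets was above control at 48 h in MDA-MB-231, with 12 of 29 members called in a fit to arrays that may be technical replicates. Camera did not call the list over both times (adjusted p = 0.187, and 0.863 with an estimated correlation). A single orientation is argued against by the lower of the list's medians by orientation, 0.47, and the centring of the arrays by the median without centring, also 0.47. A difference between single cultures cannot be told apart from an effect of gemcitabine, because there was 1 sample of MDA-MB-231 at 48 h. The hypothesis that exposure for 48 h raised these genes therefore stays untested between cultures.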
